A study of Mus musculus with 2 samples.

How the data were processed

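The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for histone H3 acetylated at lysine 9 (H3K9ac), a mark of active promoters and enhancers, in forebrain of mouse embryos of strain B6NCrl at embryonic day 15.5. Per the labels, there were 2 biological replicates, made from pools of 78 and 62 embryos of mixed sex, with fragments of 300 to 500 bp. The replicates form 1 group, and the labels give no second condition, so no test between conditions was made. A pooled replicate averages over its embryos, and the spread between embryos is not measured.

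The authors deposited 4 peak lists on mouse genome build mm10, per the file headers. Each replicate has its own list, another list was called on both replicates together, and the replicated list holds a subset of the pooled peaks. By an overlap of at least 1 bp, 3083 replicated peaks met a peak in 1 replicate's own list only and 182 in neither. A replicated peak is therefore not always a peak in each replicate. The aligner, the peak caller, its settings and the rule for keeping a replicated peak are not given in the sources used here. Each peak carries its mm10 start and end, a signal value, and p and q values as −log10, all deposited by the authors. The scale of the authors' signal value is not stated in the sources used here, so signal values were compared within a list, and between the replicates by rank, with a Pearson correlation of log2 values as an alternative. The lowest −log10 p was 2.00 in replicate 1, 2.00 in replicate 2, 2.01 in the pooled list and 2.11 in the replicated list. Weak peaks are therefore included in the deposited lists, and 12.3% of replicate 1 peaks had a q value over 0.05. Peak lists give no read counts, so the depth of each library is unknown and its effect on the number of weak peaks could not be measured. Control libraries were not analysed here.

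Genes came from GENCODE M21, on the same assembly as mm10. All peak ends lay within the chromosome lengths, and 99.99% of the 20460 protein-coding symbols shared with a RefSeq table overlapped in position. The gene comparisons used 21938 protein-coding genes on the 19 autosomes, X and Y. A promoter window reached 1000 bp to each side of any annotated transcription start site (TSS). A gene's signal value is that of the highest peak in its windows. For breadth, peaks within 1000 bp of each other were merged into domains, and a gene took the broadest domain that reached 1 of its windows. Distal peaks lay more than 1000 bp from every annotated TSS and were given to the protein-coding gene with the nearest TSS. Neighbouring genes can share a peak or a domain: 2701 genes shared their highest promoter peak with another gene, so genes are not independent.

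Replicates were compared by overlap of at least 1 bp and by the Jaccard index of covered bases, with a 95% interval from 1000 draws of chromosomes. Replicated peaks were annotated in the order promoter, exon, intron, intergenic. Both were set against 100 random placements of the peaks within their chromosome, which did not avoid assembly gaps. Shares of peaks have 95% Wilson intervals, shares of genes 95% exact binomial intervals, and Cohen's kappa an asymptotic one. These intervals cover counting error only.

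The 21 gene lists held 571 entries and were fixed from textbook knowledge before the data were examined, and so were the tests and the rule for naming genes. Of the entries, 564 were protein-coding genes, and the other 7, all in the imprinted list, are non-coding and were left out of the tests. Some genes are in more than 1 list. The share of each list with a promoter peak was compared with all other genes by a two-sided Fisher's exact test. Mean distal peaks per gene were compared with 100000 random lists matched on decile of the length of genome nearest to each gene, and median breadth with 100000 random lists of genes with a peak, both by two-sided permutation tests. Random lists were drawn with replacement from genes that included the list's own members. All p values were adjusted by Benjamini-Hochberg over the 21 lists, and the smallest permutation p that could be reached was 2e-05. Genes are the units of these tests, so a p describes these lists in these pooled tissues and not the variation between animals.

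Genes are named by rule. They are the 10 with the highest promoter signal value, the 10 with the broadest promoter domain, the 10 with the most distal peaks, and, in each replicate, the 5 highest of those with a promoter peak in that replicate only. In each list they are the 3 members with the highest signal value, the 2 broadest, and members without a peak (all where there are 4 or fewer, otherwise the first 4 in alphabetical order). The text prints part of them. A gene named outside the rule is marked as such.

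The alternatives were other promoter windows (500 and 2500 bp), other overlap rules (50% of either or of both peaks), a −log10 q of at least 5, the top 20000 peaks, other merging distances, the pooled list, each replicate's own list, 1 TSS per gene, and other backgrounds. Promoter CpG observed/expected was computed from the genome sequence, taking the highest window of each gene, and genes were matched on its decile. Backgrounds matched on number of TSSs, and for breadth also on signal value and on CpG observed/expected, were chosen after seeing the data. Ties left 7 classes of genes by number of TSSs in place of 10.

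Interval functions were checked against bedtools 2.31.1, and all 7 counts compared were equal. The list tests were tested on simulated lists of 25 genes. With no effect, 1 of 420 lists was called by the promoter test and 0 of 420 by the distal test, each among 21938 genes, and 2 of 420 by the breadth test among 13919 genes. The promoter test called 13 of 20 lists with a peak at 95% of members. The breadth test called 20 of 20 lists with breadth raised 2-fold. The distal test called 5 of 20 lists with counts raised 4-fold, so it misses many lists raised in that way. Genes without a distal peak stayed without one in that simulation. How often the test calls lists where more genes have a distal peak was not measured. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.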

Results

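H3K9ac was mapped in the forebrain of mouse embryos at embryonic day 15.5, when the cortex holds dividing progenitors beside newborn neurons. The 2 replicates, pools of 78 and 62 embryos, had 49212 and 48622 peaks. The peak list called on both together had 57772 peaks over 39.3 Mb, and the replicated list 29743 peaks over 32.5 Mb. The series has 1 tissue, 1 stage and 1 mark, so the comparisons are between gene lists within the tissue and between the replicates.

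In most of the forebrain and neuronal lists, almost every member had H3K9ac at a promoter, counting any annotated TSS. Intermediate progenitor (12 of 14) and forebrain signalling genes (30 of 33) had lower shares. All 25 members of the cortical projection neuron list, all 28 of the pan-neuronal list and all 26 of the mature synapse list had a replicated promoter peak, against 63.4% of other protein-coding genes; the lowest of these 3 shares allowed by the 95% exact intervals was 86.3%. The dorsal forebrain progenitor list had a peak at 21 of 22 members, with Fezf1 the exception. The ventral forebrain and interneuron list had one at 32 of 33, with the interneuron peptide gene Sst the exception. Sst had a peak in replicate 1 only. With the 5′-most TSS only, shares were 86.4% in dorsal progenitor, 96% in projection neuron and 90.9% in ventral genes. They were 92.9% in pan-neuronal and 88.5% in synapse genes. Among dorsal progenitor genes the highest signal values were at Foxg1, a transcription factor of the telencephalon (22.8), Lhx2 (20.3) and Id4 (20.0). Among projection neuron genes they were at Pou3f2 (25.4), Foxp1 (24.8) and Bcl11b (21.6), the last a regulator of subcortical projection neurons. Nr2f1 (26.3), Zeb2 (24.0) and Meis2 (21.2) led the ventral list, and Stmn1 (34.7), Tubb3 (25.2) and Elavl3 (25.02) the pan-neuronal list.

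Another 5 lists had few promoter peaks. The Hox genes had 3 of 39 with a peak (7.69%, 95% exact interval 1.62 to 20.9%), namely Hoxa7, Hoxc6 and Hoxa1. In the replicates' own lists, Hoxc6 had a peak in replicate 1 only. The Hox share was 12.8% without replicate 1, 17.9% in the pooled peaks and 2.56% at a −log10 q of at least 5, below the background in each. Germline genes had 3 of 26, microglia and blood genes 3 of 24 (8.33% within 500 bp), liver, muscle and heart effector genes 5 of 30 (33.3% within 2500 bp of a TSS), and non-neural lineage regulators 10 of 37. Genes without a peak included Alb and Afp, secreted by liver, Cdx2, Gata4, the germline gene Ddx4, and the microglial genes Aif1, C1qa and C1qb. Several of the high values in these lists belonged to shared promoters. The peak at Gdf9 (17.0) also lay at Uqcrq, that at Actn3 (17.4) at Zdhhc24, and that at Foxa3 (19.3) at Sympk.

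In two-sided Fisher's exact tests against all other protein-coding genes, adjusted over the 21 lists, 10 lists were above the background and 5 below. Adjusted p was 3.97e-05 for cortical projection neuron, 1.02e-05 for pan-neuronal, 2.33e-05 for ventral forebrain, 0.00183 for dorsal progenitor and 2.35e-05 for mature synapse genes in the exact tests. Cell cycle, housekeeping and chromatin acetylation genes had a peak at all 30 members each (exact test, adjusted p = 4.08e-06), imprinted genes at 20 of 22 (exact test, adjusted p = 0.00926) and forebrain signalling genes at 30 of 33 (exact test, adjusted p = 0.00128). On the low side the adjusted p was 9.04e-12 for Hox, 6.53e-07 for germline, 1.92e-06 for microglia and blood, 1.34e-06 for liver, muscle and heart, and 1.92e-05 for non-neural regulator genes in the exact tests. Intermediate progenitor (12 of 14), astrocyte (12 of 17), oligodendrocyte (9 of 18), vascular (15 of 28), choroid plexus (8 of 14) and midbrain, hindbrain and diencephalic regulator genes (27 of 38) did not pass the exact test. Hoxa genes lie side by side on chromosome 6, and the Hox tests and intervals treat such neighbours as independent. The p values of the Hox list may therefore be too small. Matching on promoter sequence ended most of the calls that the exact tests gave. Against genes matched on promoter CpG observed/expected, 3 of the 10 lists stayed above in permutation tests: cortical projection neuron (adjusted p = 0.0106), pan-neuronal (adjusted p = 0.0106) and mature synapse genes (adjusted p = 0.000504). The other lists of the 10 had matched shares of 90.0 to 95.4%, which left the test almost no room above. Cell cycle, housekeeping and chromatin acetylation genes, with a peak at every member, did not pass it (permutation tests, adjusted p = 0.700, 0.337 and 0.446). These lost calls therefore do not show that CpG content accounts for the high shares. In the same permutation tests the Hox, germline and non-neural lists stayed below (adjusted p = 0.000105 each, from a p of 2e-05, the smallest they can give), microglia and blood (adjusted p = 0.303) and liver, muscle and heart genes (adjusted p = 0.201) did not, and the midbrain, hindbrain and diencephalic regulators fell below their matched genes (71.1% against 93.4%, adjusted p = 0.000105). Against all other genes the same regulators passed the exact test in the pooled peaks (84.2%, adjusted p = 0.0209) and without replicate 1 (81.6%, adjusted p = 0.0364). Imprinted genes no longer passed the exact test with the 5′-most TSS only (77.3%, adjusted p = 0.166) or the permutation test on genes matched on number of TSSs (adjusted p = 0.0579), and intermediate progenitor genes passed the exact test within 2500 bp (92.9%, adjusted p = 0.0336) and the permutation test on genes matched on number of TSSs (adjusted p = 0.0201).

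**Figure D1:**
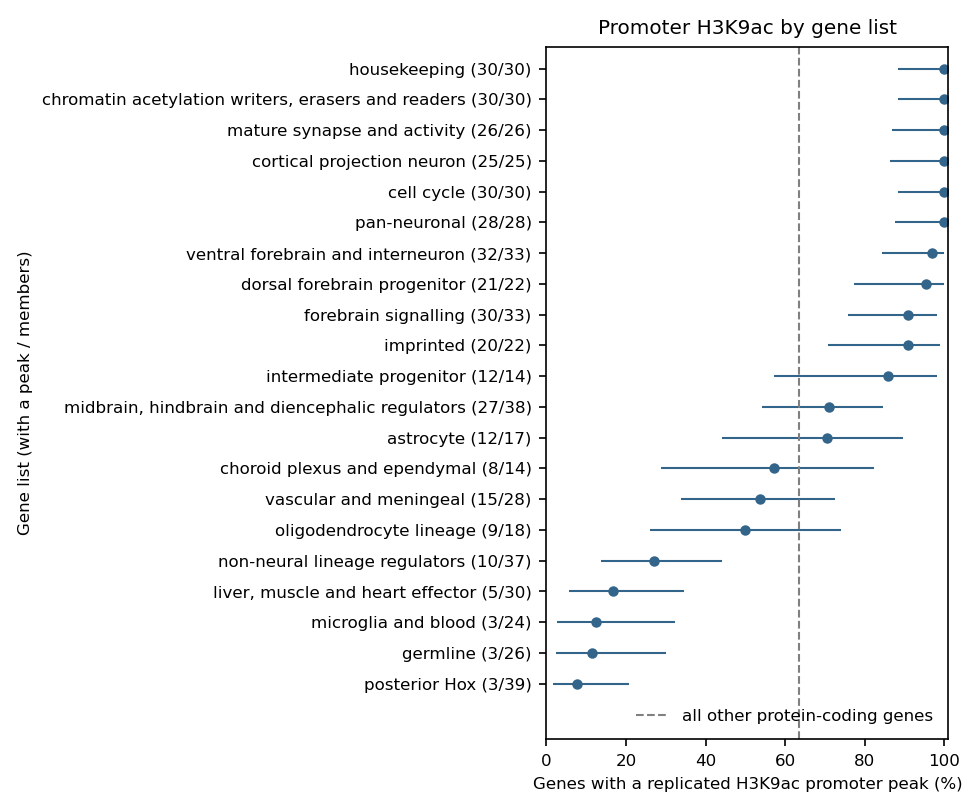
Percentage of each gene list (vertical axis) with a replicated H3K9ac peak within 1000 bp of a TSS (horizontal axis). Points are shares of members, bars 95% exact binomial intervals, and the dashed line the share of other protein-coding genes; the Hox list lies lowest at 7.69% and 6 lists lie at 100%.

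H3K9ac spread furthest around promoters of forebrain regulators. The median domain of the 13919 genes with a promoter peak was 1863 bp (quartiles 1280 and 2609 bp). It was 5911 bp in the dorsal progenitor list, 5602 bp in the projection neuron list, 5600 bp in the ventral list, 4059 bp in the pan-neuronal list and 3617 bp in the intermediate progenitor list. The broadest promoter domain, 31632 bp on chromosome 1 from 42682959 to 42714590 (mm10), covered Pou3f3, a POU-domain factor of upper-layer neurons. A domain of 29308 bp on chromosome 12 (49372932 to 49402239) covered Foxg1 and its neighbour Gm43517. Bcl11a (27820 bp, shared with A830031A19Rik), Nfib (26855 bp), Nfix (25628 bp) and Meis2 (24193 bp) followed. Dlx1 and Dlx2, adjacent homeobox genes of the ventral forebrain, shared 22322 bp on chromosome 2 (71524711 to 71547032). Signal values at these genes were 21.3 at Pou3f3, 22.8 at Foxg1, 22.6 at Bcl11a, 20.3 at Nfib, 21.02 at Nfix and 21.2 at Meis2, and lower at Dlx1 (11.7) and Dlx2 (11.2).

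In two-sided permutation tests, adjusted over the 21 lists, 10 lists were broader than random genes with a peak and 8 narrower. Adjusted p was 6e-05, which rests on the smallest permutation p that could be reached, for the dorsal progenitor, projection neuron, ventral and pan-neuronal lists, and 0.000607 for intermediate progenitor genes. Forebrain signalling genes (median 3182 bp), led by the Notch ligand Dll1 (9163 bp) and Wnt7b (7947 bp), were also broader (permutation test, adjusted p = 6e-05), as were imprinted genes (2897 bp, permutation test, adjusted p = 0.00193). Peaks of the midbrain, hindbrain and diencephalic regulators were narrow (724 bp, permutation test, adjusted p = 6e-05), and so were those of vascular (835 bp, or 1346 bp in the pooled peaks, permutation test, adjusted p = 6e-05) and oligodendrocyte genes (688 bp, permutation test, adjusted p = 0.00063). Against genes matched on signal value, 9 lists were broader and 0 narrower in permutation tests. Housekeeping (adjusted p = 0.330) and chromatin acetylation genes (adjusted p = 0.189) lost their call in these permutation tests, and cell cycle genes gained one (adjusted p = 0.000933, and 0.0463 without replicate 2 against all genes with a peak). Housekeeping and chromatin acetylation genes also lost it in permutation tests on genes matched on CpG observed/expected (adjusted p = 0.0680 and 0.0557), as did liver, muscle and heart genes (adjusted p = 0.212). With signal value matched, at an unadjusted p under 0.05 the Hox list was narrower there (permutation test, p = 0.0472). The choroid plexus call was lost without replicate 1 (permutation test, adjusted p = 0.0545) and without replicate 2 (adjusted p = 0.0861), and the microglia and blood call, on 3 genes, in the pooled peaks (1141 bp, permutation test, adjusted p = 0.106) and without replicate 1 (1137 bp, permutation test, adjusted p = 0.323), and on genes matched on CpG (adjusted p = 0.209) or number of TSSs (adjusted p = 0.105). Astrocyte genes, with no call, were narrower in the pooled peaks (1056 bp, permutation test, adjusted p = 0.00413).

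**Figure D2:**
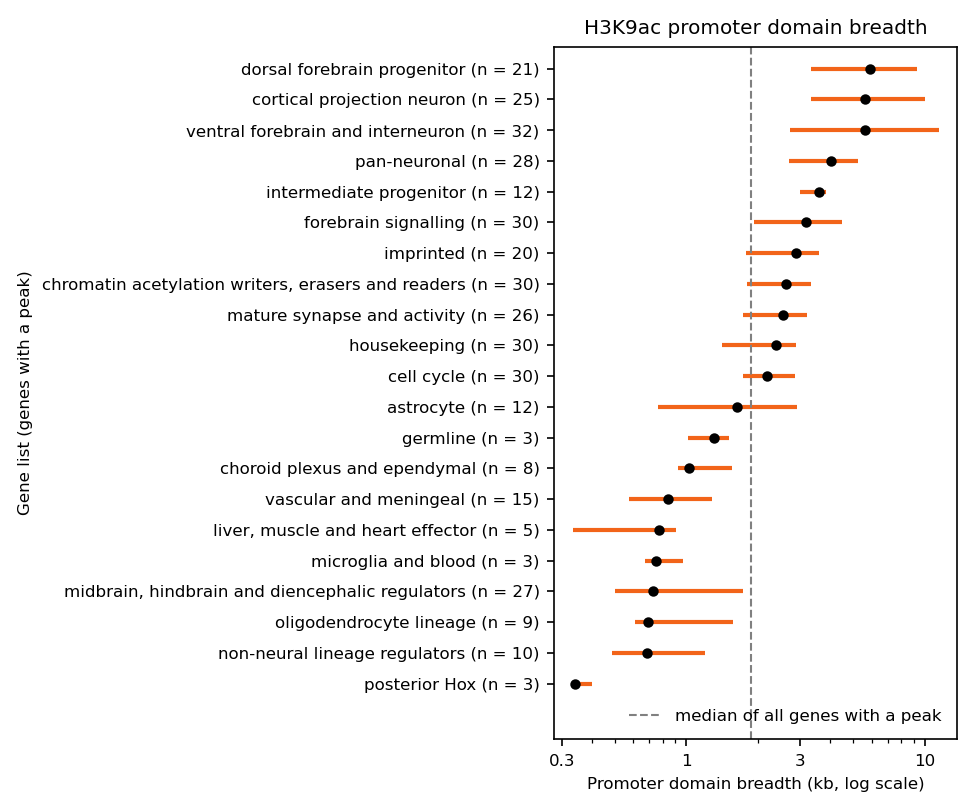
Breadth in kb (horizontal log axis) of the H3K9ac domain at promoters of each gene list (vertical axis). Points are medians over genes with a peak, bars run between quartiles, and the dashed line is the median of all such genes; dorsal progenitor, projection neuron and ventral lists lie at 5911, 5602 and 5600 bp against 1863 bp.

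**Figure D3:**
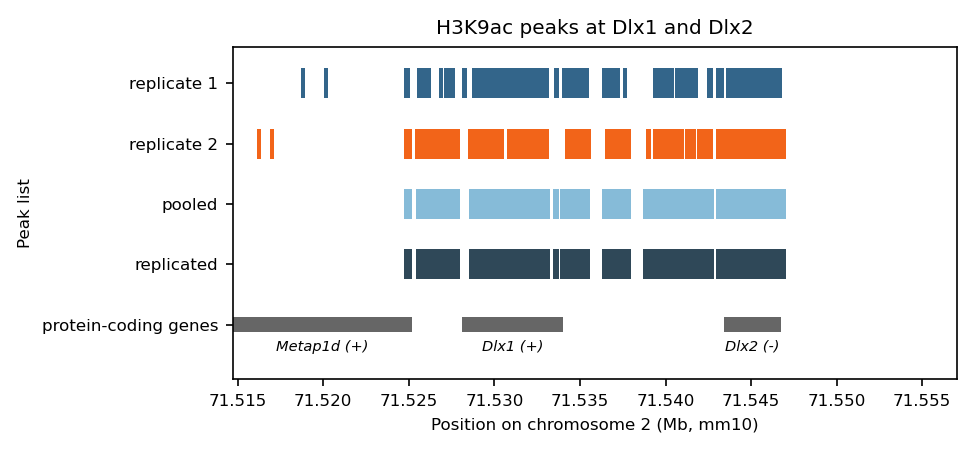
Peaks of the 4 lists (rows) and protein-coding genes around Dlx1 and Dlx2 on chromosome 2 (horizontal axis, Mb, mm10), with blocks from the start to the end of each peak or gene. Replicated peaks lie along the domain from 71524711 to 71547032, and both replicates have peaks at Dlx1 and Dlx2.

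Away from promoters, genes of the forebrain lists were also rich in peaks. Of the replicated peaks, 10316 were distal, and 5081 genes were nearest to at least 1. Distal means only more than 1000 bp from a TSS, so such a peak can also be part of a merged promoter domain. The results on distal peaks and on breadth are therefore not independent. Projection neuron genes had 5.68 distal peaks per gene (SD 5.58 over 25 genes) against 1.11 in matched lists, ventral genes 4.55 (SD 4.56 over 33 genes) against 0.920, and dorsal progenitor genes 4.32 (SD 4.29 over 22 genes) against 0.891. These levels depend on the list of peaks. Without replicate 1 the means were 10.3 in projection neuron, 7.79 in ventral and 7.18 in dorsal progenitor genes, against 2.55, 2.13 and 2.06 in matched lists, and without replicate 2 they were 11.3, 8.36 and 7.73 against 2.70, 2.23 and 2.16. In the pooled peaks they were 12.7, 9.15 and 9.77 against 3.49, 2.90 and 2.82, and beyond 5000 bp from a TSS 3.36, 2.58 and 2.46 in the replicated peaks; all 3 lists passed the permutation test in each of these. Over all protein-coding genes, the highest counts were at Gse1 (55), Tcf4 (34), Zfp608 (33), and Myt1l and Zfhx3 (25 each). None of these is in the lists, where the highest count was 23. Next came Bcl11b with 23, Prdm16 21, Zmiz1 20, Gm26897 19 and Bcor 18. Gm26897 had no replicated promoter peak. In two-sided permutation tests, adjusted over the 21 lists, these 3 lists were above matched lists (adjusted p = 0.00021, 0.00021 and 0.00168), as were pan-neuronal genes (3.02-fold, adjusted p = 0.0450) and forebrain signalling genes (2.56-fold, adjusted p = 0.0483). Intermediate progenitor genes, at 1.57 per gene, did not pass (permutation test, adjusted p = 0.151), nor at 3.71 without replicate 1 (adjusted p = 0.0719), 3.5 without replicate 2 (adjusted p = 0.100), 4.36 in the pooled peaks (adjusted p = 0.0888) or 0.857 beyond 5000 bp (adjusted p = 0.359). No list was below; at an unadjusted permutation p under 0.05 there was also none. The pan-neuronal and signalling calls were lost where distal meant over 2500 bp from a TSS (permutation tests, adjusted p = 0.0802 each) or over 5000 bp (0.276 and 0.183), and the signalling call also in the pooled peaks (adjusted p = 0.0693) and without replicate 2 (adjusted p = 0.0657). Their folds were 2.71 and 2.47 over 2500 bp and 2.17 and 2.29 over 5000 bp. For signalling genes the fold was 1.95 in the pooled peaks and 2.03 without replicate 2. Below the matched or whole background were germline genes in the pooled peaks (0.385 per gene, permutation test, adjusted p = 0.0234) and Hox genes against all genes (0.0513 per gene, permutation test, adjusted p = 0.00875).

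Most replicated peaks lay at promoters. Within 1000 bp of a protein-coding TSS were 17967 of 29733 (60.4%, 95% Wilson interval 59.9 to 61.0%), against a mean of 5.74% in random placements. Exons held 4.70%, introns 15.8%, and intergenic sequence the other 5679 peaks, all by protein-coding genes only. With all annotated genes, 3899 peaks (13.1%) were intergenic. Promoter peaks had a median signal value of 10.8 and a median width of 1203 bp, against 3.31 and 449 bp in introns. The highest values in the genome were at Actg1, which encodes a cytoplasmic actin (40.5), Mdm2 (39.1), Srsf6 (37.96), Tuba1a (37.9, a peak shared with Gm49450), Map4k4 (37.3), Adnp (36.6), Dchs1 (36.4), Kmt5b (36.3) and Cdc27 (36.1, a peak shared with Myl4). In each replicate's own list the promoter share was lower, at 45.1% in replicate 1 and 46.1% in replicate 2, and in the pooled list it was 39.0%.

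The replicates differed in their weak peaks. Of replicate 1 peaks 61.8% overlapped a replicate 2 peak by at least 1 bp, and of replicate 2 peaks 63.1% overlapped replicate 1, against 2.31% when replicate 1 peaks were placed at random. At a −log10 q of at least 5 in both lists the shares were 89.2% and 88.5%. Of the weakest replicate 1 peaks, with −log10 q under 2, 23.8% were shared, and all 5733 with a value of 50 or more were. Unshared peaks of replicate 1 had a median width of 213 bp and lay at promoters in 14.9% of cases, against 667 bp and 63.9% for shared peaks. Across the 30395 shared peaks, which are not independent, signal values of both replicates had a Spearman correlation of 0.772. The replicated list kept 51.5% of the pooled peaks, and 95.8% of those with a −log10 q of at least 5. Kept peaks had a median −log10 q of 22.8 and width of 826 bp, and peaks not kept 2.15 and 216 bp. Both replicates overlapped 26373 pooled peaks by at least 50% of either peak, and all of these were kept. A further 3370 kept peaks did not meet that rule.

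**Figure D4:**
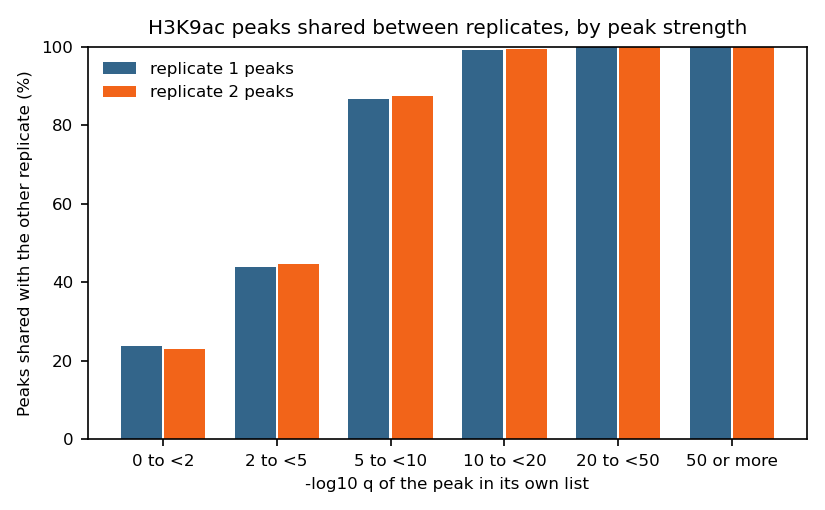
Percentage of each replicate's H3K9ac peaks that overlap a peak of the other replicate by at least 1 bp (vertical axis), by −log10 q of the peak in its own list (horizontal axis); bar colours mark the replicate. The share rises from 23.8% and 23.0% in the lowest class to 100% in the highest.

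Called gene by gene, the replicates differed little. Both had a promoter peak at 13822 genes and neither at 7492, while 268 genes had one in replicate 1 only and 356 in replicate 2 only (Cohen's kappa 0.938). All projection neuron, pan-neuronal and synapse genes had a peak in both. Genes with a peak in 1 replicate only included 7 of the 38 midbrain, hindbrain and diencephalic regulators, among them Barhl1, Gata3 and Lmx1b, 5 of 39 Hox genes, 5 of 37 non-neural regulators and 4 of 18 oligodendrocyte genes, among them Mobp. By signal value in their own replicate, the strongest such genes were 1700017N19Rik (18.3), Tmem88b (17.8), Zkscan7 (17.0), Gckr (15.9) and Ushbp1 (11.8) in replicate 1. In replicate 2 they were Sftpc (22.9), AC140267.1 (16.6), Pygm (8.81), Tnnc1 (6.30) and Gm30191 (6.07). Of these 10 genes, 1700017N19Rik and Ushbp1 had no replicated promoter peak. The replicated peak at Gckr was shared with Fndc4, that at Sftpc with Bmp1, that at Pygm with Rasgrp2 and that at Tnnc1 with Nisch. The 624 genes with a peak in 1 replicate only had a median signal value of 3.13, against 12.4 for genes with a peak in both, and 141 had a replicated promoter peak. All peaks with a −log10 q of 20 or more overlapped a peak of the other replicate. A peak that strong counts in 1 replicate only where the overlapping peak of the other ends outside the promoter window. With 1 library per replicate, differences between them have no test.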

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

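Long non-coding RNA genes were outside the comparisons above, and 877 of the 10155 annotated had a replicated peak within 1000 bp of a TSS and outside every protein-coding promoter window. In 20 random placements of the peaks a mean of 303.9 and at most 338 did. The highest signal values were at 1810026B05Rik (33.9), Mir9-3hg (31.0), the host gene of a microRNA of neural progenitors, and C130071C03Rik (28.1), which shares its peak with Gm26803. The Mir9-3hg peak covered 16117 bp on chromosome 7 (79496205 to 79512321, mm10). Small nucleolar RNA host genes Snhg5 (25.5), Snhg8 (24.6) and Snhg6 (23.6) were also among the 10 highest. These genes were chosen by signal value after the data were seen.

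Unplaced or unlocalized scaffolds, which the gene annotation used here leaves out, held 10 replicated peaks, with a signal value of up to 12.25. These and the long non-coding RNA genes stand here as signal outside the gene comparisons. No explanation was tested for either result.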

How the results depend on the processing

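The share of peaks shared, for replicates 1 and 2, was 57.7% and 59.0% at 50% of either peak, 45.6% and 46.1% at 50% of both, 89.2% and 88.5% at −log10 q of at least 5, 88.5% and 89.1% for the top 20000 peaks, and 59.7% and 60.6% with peaks within 500 bp merged. Under the last 3 the Jaccard index was 0.758, 0.754 and 0.636, against 0.611. The correlation of signal values was 0.891 for partners at 50% of both lengths, 0.786 as Pearson on log2 values and 0.763 at −log10 q of at least 5. Both replicates overlapped 46.2% of pooled peaks by 1 bp, 45.7% at 50% of either, 36.5% at 50% of both, and 91.5% of those at −log10 q of at least 5, of which 95.8% were kept. The promoter share was 57.2% within 500 bp, 67.9% within 2500 bp, 39.0% of pooled peaks, 57.2% by peak midpoint and 65.3% with all annotated genes; replicate 1 alone and replicate 2 alone, which are also the lists left without the other replicate, ranged from 45.1% to 46.1%. Cohen's kappa was 0.945 within 500 bp, 0.925 within 2500 bp and 0.948 at −log10 q of at least 5.

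Matching on CpG observed/expected left 3 lists above the background in promoter share in place of 10. The lists that lost this call had matched shares of 90.0 to 95.4%, where the test had almost no room to call a list above. CpG matching turned the regulators of midbrain, hindbrain and diencephalon below their background with a call (71.1% against 93.4%). Forebrain signalling genes lay slightly below theirs with no call (90.9% against 92.5%). Astrocyte genes, with no call, turned below at −log10 q of at least 5 (58.8%) and matched on number of TSSs (70.6%), and choroid plexus genes above under the latter (57.1%). For distal peaks, 3 lists were above in place of 5 beyond 2500 bp and 3 beyond 5000 bp, and 1 list in place of 0 was below with all genes as background and 1 with pooled peaks. The other turns were in lists with no call: mean distal peaks of choroid plexus genes within 100 kb (0.571), microglia (0.458) and vascular genes (0.607) against all genes, oligodendrocyte (0.222) and chromatin acetylation genes (0.233) beyond 5000 bp, oligodendrocyte (1.5), choroid plexus (1.57) and non-neural genes (1.76) in pooled peaks, choroid plexus (0.286) and chromatin acetylation genes (0.267) at −log10 q of at least 5, non-neural genes without replicate 1 and without replicate 2 (1.22 to 1.24), and oligodendrocyte (1) and choroid plexus genes (1.21) without replicate 2. Matched on signal value, 0 lists in place of 8 were narrower, and astrocyte (1635.5 bp), vascular (835 bp) and choroid plexus genes (1022.5 bp) turned broader than their background with no call. The backgrounds matched on number of TSSs, and on signal value and CpG for breadth, were chosen after seeing the data. Over single lists, 170 of 189 promoter, 146 of 168 distal and 145 of 168 breadth values kept their direction and side of the threshold. Of the others, 10 promoter, 6 distal and 17 breadth values lost their call in the same direction, and 4, 2 and 3 gained one. Replicate overlap, the signal correlation and genes in 1 replicate only need both replicates and have no value with 1 left out. Except where a background's own construction sets the value, the cause was not tested. Depth is unknown, and how far it sets the number of weak peaks stays open.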

Other observations

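Of 7 non-coding members of the imprinted list, 5 had a replicated promoter peak: Meg3 (signal value 12.03), Peg13 (9.98), Airn (6.62), Kcnq1ot1 (5.74) and Mirg (3.08). H19 and Rian had none. Among protein-coding imprinted genes, Gnas (21.2), Ube3a (19.7) and Igf2r (16.2) were highest, and Igf2 and Ndn had no replicated peak. Olfactory receptor genes, a set chosen after its values were seen, had a promoter peak at 2 of 1135 genes (0.176%, 95% exact interval 0.0214 to 0.635%).

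The tests of breadth against genes matched on signal value, CpG or number of TSSs were chosen after the breadth result was seen, and so was the use of other lineages' CpG-matched values for the regulators. All 3 patterns were noticed in the data that test them, and the explanations weighed concern sequence, annotation, peak calling and the make-up of the pooled tissue. The design has no second group, so no biological explanation that rests on a group was tested.

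Broad promoter domains marked 5 lists picked for their breadth: dorsal progenitor, intermediate progenitor, projection neuron, ventral forebrain and pan-neuronal genes. If breadth follows peak height, matching on signal value should have ended most calls, but 5 of 5 lists kept an adjusted permutation p under 0.05 and a median over 1.5 times that of matched genes. The same held for 5 of 5 lists matched on CpG observed/expected, against CpG-rich promoters, and for 5 of 5 matched on number of TSSs, against several annotated TSSs per gene. These tables argue against each of the 3 as the whole cause. A gene's highest peak can lie outside its broadest domain, as at Nfix. Matching on signal value therefore did not always match the height of the domain measured. CpG was matched on the highest promoter window of each gene, so how far CpG-rich sequence reaches was not tested. The peak caller's own rule for joining enriched stretches stays open.

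Regulators of midbrain, hindbrain and diencephalon had promoter peaks at 27 of 38 members, with a median signal value of 3.82. That share did not pass the exact test against other genes (71.1% against 63.4%, adjusted p = 0.443). The diencephalon belongs to the forebrain, and its regulators were not told apart from the rest of the list. Hindbrain tissue in the dissection, if plentiful, would bring peaks at Hox genes of paralogue groups 1 to 4. Of these, 8.33% had a replicated peak (1 of 12, upper exact 95% bound 38.5%). Hoxa4 and Hoxd1 had a peak in 1 replicate only. Hox-expressing hindbrain is therefore argued against as a large part of the tissue. What share of hindbrain would give these genes a peak is not known, so a small admixture stays open. Midbrain or diencephalic tissue was not tested. Peaks close to the calling threshold stay open: 88.9% of members with a peak (24 of 27, 95% exact interval 70.8 to 97.6%) kept one at −log10 q of at least 5, but so did 98.5% of all genes with a peak, and 7 of 38 members had a peak in 1 replicate only, against 2.84% of all genes. Genes matched on CpG observed/expected had a peak in 93.4% of cases against 71.1% of the list, which met what was set beforehand for CpG-rich promoters that carry peaks whatever the lineage. As a rule for every lineage, that is argued against by 3 of the 5 lists found above to have few promoter peaks. Hox (7.69% against 90.9%), non-neural (27.0% against 77.6%) and germline genes (11.5% against 61.7%) lay far below their own CpG-matched genes (permutation tests, adjusted p = 0.000105 each). Microglia and blood genes (adjusted p = 0.303) and liver, muscle and heart genes (adjusted p = 0.201) did not pass that permutation test. Nor did vascular (53.6% against 57.3%), choroid plexus (57.1% against 61.9%), oligodendrocyte (50% against 56.15%) and astrocyte genes (70.6% against 60.2%). For the regulators themselves, CpG-rich promoters as a source of their peaks stay open.

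Pooled peaks on the X chromosome were kept in the replicated list in 76.4% of cases (809 of 1059), against 51.0% on autosomes, where single chromosomes ranged from 47.1% to 56.1%. GC content of the peaks is argued against, since matching on it left a gap of 22.9 of 25.4 percentage points. The share of promoter peaks, higher on the X, left 13.4 points once matched, so it may account for part of the gap and its full weight stays open. In matched deciles of signal value, the median −log10 p on the X was 0.873 times the autosomal one, and single autosomes ranged from 0.988 to 1.01 times the others. Pooled peaks on the X had a median signal value of 5.22, against 3.00 on autosomes, and stronger peaks were kept more often. The gap was not matched on signal value, so the weight of peak strength stays open. Fewer copies of the X chromosome in a mixed-sex pool, with fewer reads behind a given signal value and so fewer weak peaks called, may be a source of the gap.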
